A study of Homo sapiens with 8 samples.

How the data were processed

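Per the labels' protocols, total RNA from biologically independent cultures of H1 human embryonic stem cells was extracted with Trizol, commercial spike-in RNAs were added, linkers were ligated to the 3′ and then the 5′ ends, and the products were size-selected on gels, amplified by PCR and sequenced as single-end reads. The labels name 4 genotypes with 2 libraries each: wild type, Dicer-S1344L homozygous, Dicer-S1344L hemizygous and Dicer-null. Per the series description, the mutant lines were made with CRISPR-Cas9. Per the submitters' processing notes, the authors used cutadapt and limma (versions not given) and the hg38 genome build; the aligner, the counting method, the miRNA annotation, any filter and the scaling are not given in the sources used here.

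The deposited table holds log2 RPM (reads scaled to a denominator, also written CPM) with 0.5 of a read added, 1 column per library per the file headers. The unit was read from the values: in each library the lowest values step as whole reads plus 0.5 over 1 denominator do, so the reads could be computed back. The largest distance of a recovered count from a whole read was 7.31e-09. The analysis had been planned for CPM, and the deposited log2 values were therefore turned back to RPM. The denominators, between 751353 and 1399490, are not the totals of the miRNA reads, which lie between 137655 and 2725756, and how the authors set them is not stated. The product over the libraries of denominator over miRNA reads was 1.02. The table holds 594 miRNAs and 0 spike-in entries. Of these, 227 are named 5p, 300 are named 3p and 67 name no arm; the last hold between 1.58% and 12.1% of the reads of a library.

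The precision of a value follows from its depth. Reads of 1 correspond to between 0.715 and 1.33 RPM, a count of 0 allows up to 3 reads, and shares per library carry 95% Wilson intervals, which cover counting error only. Chi-square over degrees of freedom between replicate libraries was 85.8, 10.6, 70.3 and 33.2 in the wild-type, homozygous, hemizygous and null pairs, so the spread between replicates exceeded counting error in each.

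Fold changes were tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with 1 model of group means over all 8 libraries and moderated variances with a trend, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. All 594 miRNAs passed the filter of at least 5 RPM in at least 2 libraries. The estimated prior was infinite, so miRNAs of 1 level share 1 spread. Errors on fold changes are standard errors from that model and errors on RPM are standard deviations over 2 libraries. The comparisons were homozygous, hemizygous and null against wild type, hemizygous against homozygous, and each S1344L genotype against null. For 186 hairpins with both arms in the table, the log2 of (3p RPM + 1) over (5p RPM + 1) was tested in the same way. Arms were paired by name, so a name that covers more than 1 locus, such as let-7a, counts as 1 hairpin. Arm sets and lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the sets within a comparison; camera asks whether a set lies above or below the other miRNAs, and fry whether it moves on balance one way. An arm was called the more abundant of its hairpin by its mean log2 RPM in the wild type. This grouping therefore uses values that also enter the fold changes against the wild type. The 5p share of RPM was compared with an exact two-sided permutation test. The overlap of the S1344L genotypes was set beside 100 simulated draws with no effect and the same wild-type libraries.

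The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The lists were let-7 guides and passengers, the 3p and 5p arms of miR-302 with miR-367, miR-371-373, the 5p and 3p guides of miR-17-92 and its paralogs, the 5p and 3p arms of the chromosome 19 cluster and of the DLK1-DIO3 cluster, mirtrons, other Drosha-independent miRNAs, miR-451, and neural, mesoderm and endoderm, fibroblast-enriched and p53-linked miRNAs. Named miRNAs are the 10 largest rises and the 10 largest falls per comparison among those past the threshold with non-overlapping groups and a mean of at least 50 RPM in 1 group, the 5 most abundant of the wild type, up to 4 members per list, and miR-451a. List members are named for the homozygous comparison only, apart from miR-451a, and given as counts elsewhere. A miRNA named outside this rule is said to be an exception or was chosen after its values were seen. Abundant arms are those with at least 500 RPM in the wild type.

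Alternatives tried were pseudocounts of 0.5 and 5, filters of none and 50 RPM, median-ratio, upper-quartile and quantile scaling, fits of fewer libraries, other variance options, array weights, an adjusted p under 0.01, a log2 fold change of at least 1, a replicate block, and leaving out each library. Added after seeing the data were the deposited log2 values as they stand, scaling to each library's own miRNA reads, voom weights on recovered reads, an estimated correlation after median-ratio scaling, and the set tests without hemizygous replicate 1. Where leaving out a library leaves a group with 1, the lone sample is assumed to vary like the other groups.

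Hairpins were placed on hg38 with GENCODE 29, in Python 3.11.15, by matching miRNA names to annotated miRNA genes: 581 of the 594 (97.8%) had at least 1 match, and host genes and overlapping small RNA genes come from the same annotation. The tests were tested on simulated data for homozygous against wild type, with 594 miRNAs of which 200 changed and a coefficient of variation of 20%: at log2 changes of 1, 2 and 4, 74.6%, 98.5% and 100% were recovered with their sign, and 6 of 188 calls were false. For 186 simulated hairpins of which 60 shifted, 30%, 95% and 100% were recovered at shifts of 1, 2 and 3, and 1 of 46 calls was false. The replicate spread on the deposited scale is wider than in that simulation.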

Results

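Small RNAs were sequenced in 8 libraries of H1 human embryonic stem cells, an established pluripotent line, with 2 libraries in each of 4 groups. The groups were wild-type cells, cells homozygous for S1344L, cells hemizygous for S1344L, and Dicer-null cells. Dicer is the enzyme that cuts a miRNA hairpin into its 5p and 3p arms, and S1344L is a substitution found repeatedly in tumours. The 594 mature miRNAs measured held 2680973 and 2725756 reads in the wild-type libraries, 2289926 and 1814568 in the homozygous, 1000101 and 1833057 in the hemizygous, and 165317 and 137655 in the null. Values are RPM (reads scaled to the deposited denominator of each library), and that denominator was not the total of the miRNA reads. The miRNA reads came to 2.09 and 2.33 times the denominator in the wild-type libraries, 2.43 and 2.18 in the homozygous, 0.729 and 2.42 in the hemizygous, and 0.118 and 0.183 in the null. Hemizygous replicate 1 therefore stood apart, and its miRNAs lay below those of replicate 2 by a median of 1.93 on the log2 scale. Across miRNAs, which are not independent replicates, the replicate libraries correlated at r = 0.973, 0.993, 0.950 and 0.968 in the wild-type, homozygous, hemizygous and null pairs. A count of 0 allows up to 3 reads, from 2.14 to 3.99 RPM depending on the library; 64 and 56 miRNAs had a count of 0 in the null libraries and at most 3 in any other library. Intervals and these limits cover counting error only, since the labels name no molecular identifiers.

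The first question was how S1344L changes the balance between the arms. In wild-type cells, 5p arms held 33.0% ± 1.54 (SD, n = 2) of the RPM of all 5p- and 3p-named miRNAs. The share was 10.9% ± 0.371 in homozygous cells and 10.5% ± 1.19 in hemizygous cells, which is -22.1 and -22.5 points from the wild type, and 26.8% ± 1.93 in null cells, -6.12 points from it. Per library the shares (with 95% Wilson intervals) were 31.9% (31.8 to 31.9) and 34.0% (34.0 to 34.1) in the wild type, 11.2% (11.1 to 11.2) and 10.6% (10.6 to 10.7) in the homozygous, 9.62% (9.56 to 9.67) and 11.3% (11.3 to 11.3) in the hemizygous, and 25.5% (25.3 to 25.7) and 28.2% (27.9 to 28.4) in the null libraries. The exact two-sided permutation test gave p = 0.333 for each mutant against the wild type, the smallest value that 2 against 2 libraries allow. The homozygous and hemizygous shares differed from the wild type by far more than the spread within groups. Without the 5 most abundant miRNAs, the differences were -33.1 points in homozygous and -32.8 points in hemizygous cells, while the null cells turned to 3.75 points above the wild type.

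**Figure D1:**
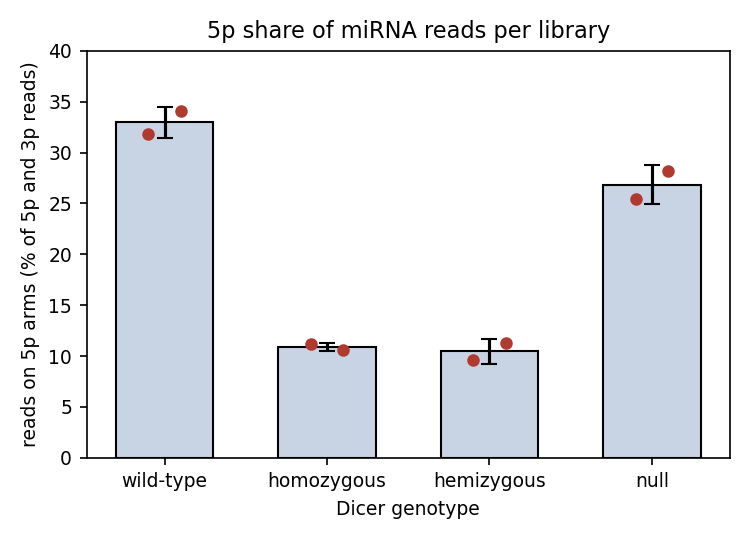
Share of 5p arms in the RPM of all 5p- and 3p-named miRNAs (percent, vertical axis from 0) in each of the 8 libraries by genotype, with the group means. The 4 S1344L libraries lie between 9.62% and 11.3%, below the wild-type libraries at 31.9% and 34.0% and the null libraries at 25.5% and 28.2%.

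In homozygous S1344L cells, 5p arms were depleted and a set of normally minor 3p arms gained. The largest fall was in miR-345-5p, a miRNA with growth-restraining roles in tumours, which went from 2020.0 ± 748 to 31.4 ± 16.3 RPM (log2 fold change -6.01 ± 1.00 SE, n = 2 per group, adjusted p = 1.45e-06). let-7a-5p, the guide that drives differentiation, went from 6062 ± 814 to 148 ± 17.8 RPM (-5.35 ± 0.95, adjusted p = 3.82e-06), and miR-34a-5p, a p53 target that slows the cell cycle, went from 3428 ± 139.9 to 95.7 ± 25.7 RPM. miR-7-5p, which acts on growth-factor signalling, fell by 5.65. The largest rise was in miR-16-2-3p, the usually discarded strand of a cell-cycle-restraining miR-16 hairpin, from 393 ± 146 to 8735 ± 1159 RPM (4.52 ± 0.90). miR-20a-3p, the passenger strand of a growth-promoting miR-17-92 hairpin, rose from 2245 ± 767 to 30077 ± 2122 RPM (3.78 ± 0.83, adjusted p = 0.000113). The next falls, in miR-218-5p, miR-744-5p, miR-525-5p, miR-1296-5p, miR-185-5p and miR-1908-5p, ran from -5.46 to -5.06. Of the other large rises, those of miR-450a-1-3p, miR-33b-3p, miR-30d-3p, miR-503-3p and miR-125a-3p ran from 3.44 to 4.04, and those of miR-30c-2-3p, miR-135a-3p and miR-150-3p rested on 3 to 6 reads per wild-type library. The 10 largest rises were all 3p arms and the 10 largest falls all 5p arms.

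Of the 594 miRNAs, limma called 191 changed in homozygous cells, 59 up and 132 down. The errors pool the spread of all 8 libraries, so they also carry that of the hemizygous and null pairs. The median log2 difference of replicate 2 from replicate 1 was 0.227, -0.231, 1.93 and 0.795 in the wild-type, homozygous, hemizygous and null pairs. A miRNA that did not pass is therefore not shown to be unchanged. Among 227 5p arms 111 fell and 1 rose, with a median of -2.25; among 300 3p arms 56 rose and 13 fell, with a median of 0.68. The 1 rising 5p arm was miR-320a-5p (2.63 ± 0.99, from 19.5 to 78.9 RPM), named because it was the exception. It had 4 and 41 reads in the wild-type libraries, was at 1.12 without wild-type replicate 1, and no longer passed without that library or either homozygous library. The split depended on the scaling. The median of all miRNAs moved from -0.04 to -0.10 when each library was scaled to its own miRNA reads, to 0.14 with median-ratio factors, 0.29 with quantile normalization and 0.82 with upper-quartile scaling, and the calls became 113 up and 200 down, 152 and 186, 189 and 165, and 254 and 150. In each of these, at least 187 of the 191 calls were kept, and from 123 to 149 of the 5p arms fell against 5 to 25 that rose. A group left with 1 library has a larger error, so a call lost there need not rest on the library left out. The count also moved when 1 library was left out. It was 69 without wild-type replicate 1, 67 without wild-type replicate 2, 63 without homozygous replicate 1, 36 without homozygous replicate 2 and 288 without hemizygous replicate 1. In the smallest of these, 29 5p arms fell and 5 3p arms rose. The rises of miR-16-2-3p, miR-20a-3p and miR-30c-2-3p passed in all of these, while those of the other 7 did not pass in at least 3 of them.

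In homozygous cells 5p arms lost reads both where they are the usual guide and where they are the passenger. Where the 5p arm was the more abundant arm of its hairpin in the wild type, 61 of 115 fell (median -2.57, camera adjusted p = 8.50e-15), and where it was the less abundant, 36 of 71 fell and 1 rose (median -2.34, adjusted p = 3.44e-08). The less abundant 3p arms rose in 35 of 115 cases and fell in 3 (median 1.48, adjusted p = 7.78e-17), whereas 0 of the 71 more abundant 3p arms rose and 1 fell (limma; 0 and 3 at an unadjusted p under 0.05; median 0.13, camera adjusted p = 0.209). The grouping by the more abundant arm uses the wild-type values that also enter these changes. Part of the contrast between the less and the more abundant 3p arms can therefore follow from the grouping. The 3 set calls were lost with an estimated correlation (adjusted p = 0.788, 0.850 and 0.788 with an estimated correlation). The same applied to all 5p arms (adjusted p = 2.08e-30) and all 3p arms (adjusted p = 5.51e-24), both at adjusted p = 0.788 with an estimated correlation on the deposited scale. After median-ratio scaling, an alternative chosen after seeing the data, they passed at 0.000752 and 0.0035 with an estimated correlation. fry, which tests for a move on balance one way, called 0 of 18 sets (adjusted p from 0.140 to 0.984; 0.158 for all 5p and 0.519 for all 3p arms). Of 109 5p arms with at least 500 RPM in the wild type, 69 fell and 23 stayed within 2-fold; of 109 such 3p arms, 7 fell, 8 rose and 67 stayed within 2-fold.

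**Figure D2:**
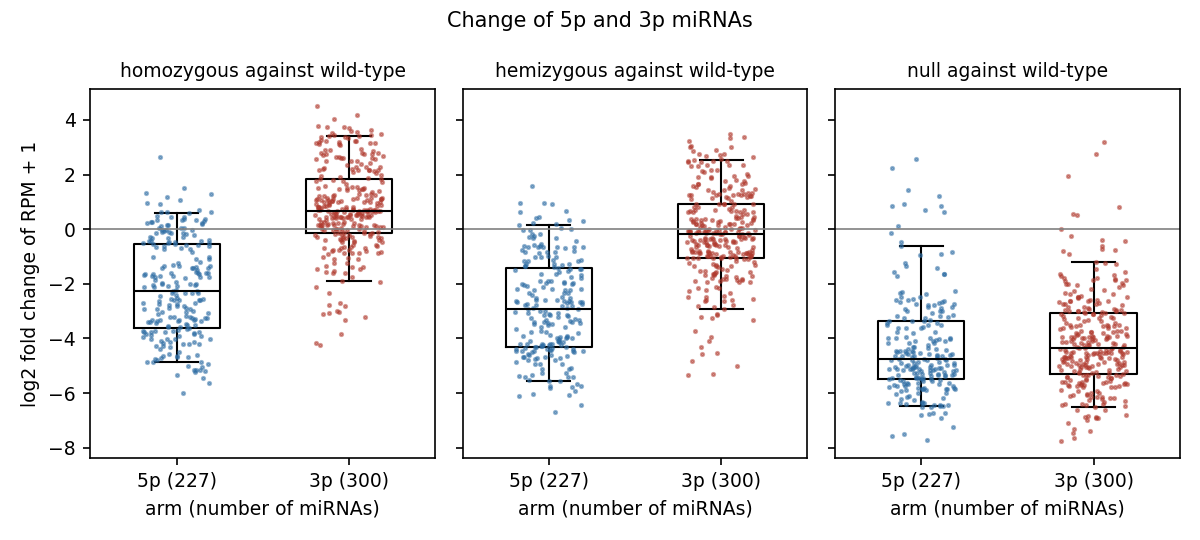
Log2 fold changes against the wild type of all 5p and all 3p arms (vertical axis, log2) in homozygous, hemizygous and null cells on the deposited scale, 1 point per miRNA, with the median of each arm. The 5p medians are -2.25, -2.93 and -4.77, and the 3p medians 0.68, -0.18 and -4.35; under median-ratio and upper-quartile scaling more 3p arms rose than fell in hemizygous cells too.

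Pluripotency miRNAs of the miR-302 cluster, which includes miR-367 (hg38 chromosome 4, 112647874 to 112648557, minus strand, in the long non-coding gene AC106864.1) showed no called change of their guide strands in homozygous cells. These 3p arms are the 5 most abundant miRNAs of the wild type, and 0 passed in limma (0 at an unadjusted p under 0.05). miR-302b-3p was at 0.43 ± 0.70, miR-302c-3p at -0.61, miR-302a-3p at 0.67, miR-367-3p at 0.40 and miR-302d-3p at 0.52. On the 5p side miR-302b-5p (-3.56 ± 0.87, adjusted p = 0.000509) and miR-302d-5p (-3.66 ± 0.92) fell, while miR-302a-5p (-0.20, turning to 0.71 under upper-quartile scaling) and miR-302c-5p (-0.84) did not pass. The oncogenic miR-17-92 cluster (chromosome 13, 91350605 to 91351391, plus strand, in MIR17HG) and its paralogs lost all 8 of their 5p guides (median -3.14, camera adjusted p = 0.000254; adjusted p = 0.788 with an estimated correlation). The 4 named here fell under each of the scalings tried. miR-17-5p went from 50240 ± 4875 to 8258 ± 1375 RPM (-2.61 ± 0.81, adjusted p = 0.00618), and miR-20a-5p and miR-106b-5p fell by 2.93 and 3.75, with miR-18a-5p between them. Some of these calls were lost when a group was left with 1 library, which gives a larger error. miR-17-5p, miR-20a-5p and miR-515-5p no longer passed without either wild-type or either homozygous library. miR-18a-5p, miR-106b-5p, miR-302b-5p and miR-302d-5p did not pass without wild-type replicate 2 or homozygous replicate 2. These losses do not show that 1 library carried a call. miR-17-5p had 60090 and 62749 reads in the wild-type libraries against 8714 and 6060 in the homozygous. miR-515-5p had 13152 and 11643 against 1134 and 938. Of the 6 3p guides in these clusters 0 passed in limma (0 at an unadjusted p under 0.05): miR-19b-3p was at 0.69, miR-92a-3p at 0.46, miR-19a-3p at 1.02 and miR-92b-3p at -0.01 (0.89 under upper-quartile scaling). In the primate-specific chromosome 19 cluster (53666679 to 53762430, plus strand), a placental and stem-cell cluster, 20 of 28 5p arms fell (adjusted p = 6.21e-08; adjusted p = 0.788 with an estimated correlation), among them miR-515-5p (-3.12) and miR-525-5p (-5.19). miR-512-5p (-0.11) and miR-498-5p (-0.52) did not pass, and miR-512-5p turned to 0.79 under upper-quartile scaling. Of its 31 3p arms 3 rose (camera adjusted p = 0.0582); the named ones, miR-520f-3p (-0.15, but 0.76 under upper-quartile scaling), miR-519b-3p (-0.14), miR-518c-3p (0.74) and miR-512-3p (1.52), did not pass. Several members of this cluster are nearly identical, so reads may be shared between them in a way the counting method, which is not stated, would decide.

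Other groups fixed in advance moved in part. The neighbouring miR-371-373 cluster (chromosome 19, 53787675 to 53788773), also linked to pluripotency, had 0 of 6 arms past the limma threshold (1 at an unadjusted p under 0.05), with miR-372-3p at 1.45, miR-373-3p at 1.29, miR-371a-5p at -1.35 and miR-371a-3p at 1.95 (adjusted p = 0.0533). let-7a-3p, the passenger of let-7a, was at 2.24 (adjusted p = 0.0698). It is the only measured member of its list, so adjusting over the list alone leaves its p unadjusted, and that p lay under 0.05. let-7a-3p also passed under some alternatives, such as median-ratio scaling and a fit of only the 4 libraries compared. Among p53-linked miRNAs 2 of 5 fell, miR-34a-5p and miR-34c-5p (-4.03), with miR-107 at -2.13 and miR-34b-5p at -0.02. Among neural miRNAs 3 of 8 fell, including miR-125b-5p (-4.01), with miR-9-5p at -0.69, miR-124-3p at 0.77 and miR-128-3p at -0.30. Of 5 mesoderm and endoderm miRNAs 1 fell, miR-192-5p (-3.51), with miR-194-5p at -1.41, miR-133a-3p at 0.50 and miR-1-3p at 0.83. Of 12 fibroblast-enriched miRNAs 2 fell, miR-222-3p (-4.24, a repressor of the cell-cycle inhibitor p27) and miR-31-5p (-3.58), with miR-21-5p at -1.62 and miR-221-3p at 0.38. Of 2 mirtrons, which form without Drosha, miR-1227-3p fell (-3.12) and miR-1237-3p was at 1.45. Of 5 other Drosha-independent miRNAs miR-320a-5p rose and miR-484 fell (-4.23), with miR-320a-3p at -1.35, miR-320b at -1.56 and miR-320c at -1.60. The Dicer-independent miR-451a was at 1.40 (adjusted p = 0.279). Of these calls, miR-320a-5p was lost without wild-type replicate 1 or either homozygous library, miR-484, miR-125b-5p and miR-34c-5p were lost without homozygous replicate 2, miR-1227-3p and miR-31-5p also without either wild-type library, and miR-192-5p without any of these or homozygous replicate 1. Adjusted over the list alone, the counts were 8 of 8 for the 5p guides of miR-17-92, 20 of 28 and 2 of 31 for the 5p and 3p arms of the chromosome 19 cluster, 1 of 1 for each let-7a arm, and otherwise the same as over all miRNAs. For the let-7a arms, each alone in its list, this means no adjustment. Members of the DLK1-DIO3 cluster, and let-7 members other than let-7a, were not analysed here.

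The scaling of a library cancels from the 3p/5p ratio within a hairpin except through the 1 RPM added to each arm, which matters where reads are few. In homozygous cells the ratio moved toward the 3p arm in most hairpins. let-7a, at -6.09 ± 0.87 on the log2 3p/5p scale in the wild type, changed by 7.59 ± 0.55 (adjusted p = 1.52e-07), so that its 3p arm outnumbered the guide. miR-20a moved by 6.71 ± 0.38, miR-17 by 5.03 ± 0.39, and the chromosome 19 hairpins miR-525 and miR-515 by 5.05 and 4.53. Of 186 hairpins with both arms measured, 150 shifted in limma, 148 toward 3p and 2 toward 5p, with a median of 3.29 (a 9.75-fold change; fry adjusted p = 5.10e-07). The hairpins with more 3p than 5p reads numbered 71 and 75 in the wild-type libraries and 128 and 131 in the homozygous. Toward 3p moved 99 of the 115 hairpins whose 5p arm was the more abundant in the wild type and 49 of the other 71. All 11 hairpins of miR-17-92 and its paralogs shifted to 3p (median 5.03, fry adjusted p = 9.37e-05), as did 26 of 28 in the chromosome 19 cluster (median 3.62) and 2 of 3 in miR-371-373, miR-371a and miR-372 (2.17), with miR-373 at 0.95. In miR-302, miR-302b (3.99 ± 0.43) and miR-302d (4.18 ± 0.43) shifted while miR-302a (0.86, adjusted p = 0.0563), miR-302c (0.23) and miR-367 (0.44) did not pass. The 2 shifts to 5p were in miR-23a (-2.07, lost without wild-type replicate 1 or homozygous replicate 2) and miR-320a (-3.98 ± 0.72). The count lay between 140 and 157 when any 1 library was left out.

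**Figure D3:**
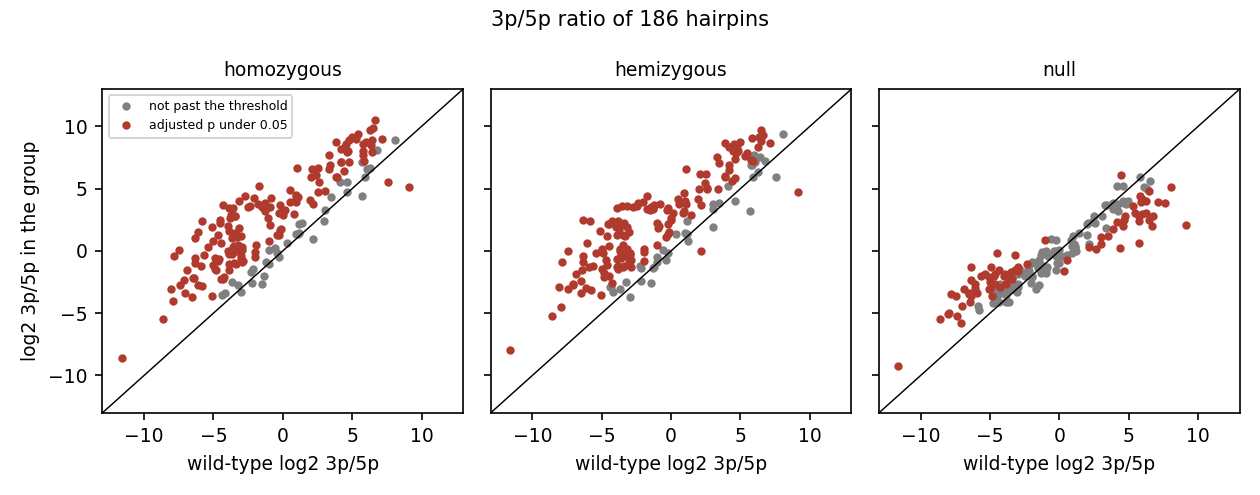
Mean log2 ratio of 3p to 5p RPM of 186 hairpins in homozygous, hemizygous and null cells, 1 panel each (vertical axis). The horizontal axis is the mean log2 ratio in the wild type. The line marks equal ratios, and colour marks hairpins at an adjusted p under 0.05 (limma). The medians per library, which are not drawn, are -1.41 and -1.33 in the wild type, 2.28 and 2.30 in homozygous, 2.05 and 1.95 in hemizygous, and -1.02 and -1.09 in null libraries.

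Hemizygous S1344L cells, which address whether a single mutant allele without a wild-type partner acts like a pair of them, also lost 5p arms. miR-345-5p fell by 6.70 (SE 1.00, adjusted p = 9.00e-09), let-7a-5p went from 6062 ± 814 to 140 ± 127 RPM (-5.80 ± 0.95, adjusted p = 1.62e-07), and miR-7-5p, miR-34a-5p and miR-218-5p fell by 6.43, 5.79 and 5.94. The other large falls, in miR-324-5p, miR-185-5p, miR-99b-5p, miR-181a-5p and miR-1307-5p, ran from -6.13 to -5.73. miR-16-2-3p (3.23 ± 0.90) and miR-20a-3p (from 2245 ± 767 to 21282 ± 17382 RPM) rose again, and the other 8 of the largest rises, in miR-150-3p, miR-135a-3p, miR-30c-2-3p, miR-135b-3p, miR-219a-2-3p, miR-15a-3p, miR-503-3p and miR-30b-3p, ran from 2.73 to 3.49. Wild-type reads were few for miR-150-3p, miR-135a-3p and miR-30c-2-3p (3 to 6 per library) and for miR-503-3p (5 and 9). The rises of miR-16-2-3p and miR-20a-3p no longer passed without wild-type replicate 1, and each of the other 8 was lost without 1 or both wild-type libraries. The abundant pluripotency guides did not pass on the deposited scale (limma). miR-302b-3p was at -0.15, miR-302c-3p at -1.58 (adjusted p = 0.0787), miR-302a-3p at 0.05, miR-367-3p at -0.46 and miR-302d-3p at -0.18; with median-ratio factors miR-302b-3p, miR-367-3p and miR-302d-3p turned to 0.97, 0.66 and 0.94. The Dicer-independent miR-451a was at 0.16.

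In hemizygous cells limma called 206 miRNAs, 24 up and 182 down. Among 5p arms 138 fell and 0 rose (limma; 0 at an unadjusted p under 0.05). Among 3p arms 24 rose and 29 fell, with a median of -0.18, while camera placed the 3p set above the other miRNAs (adjusted p = 5.59e-18) and fry found no direction for it (adjusted p = 0.814). The 5p set lay below the others (median -2.93, adjusted p = 1.29e-25), and both sets were at adjusted p = 0.838 with an estimated correlation. With fry 0 of 18 sets passed, at adjusted p from 0.0567 to 0.814, and all 5p arms were at 0.0671. The median of all miRNAs was -0.89 on the deposited scale, -0.19 on each library's own miRNA reads, 0.14 with median-ratio factors, 0.28 with quantile normalization and 0.84 with upper-quartile scaling. Calls then became 108 up and 204 down, 160 and 184, 179 and 169, and 255 and 153, and from 101 to 195 3p arms rose against 21 to 42 that fell. The count was 124 (3 up) without wild-type replicate 1, 111 (6 up) without wild-type replicate 2, 159 (10 up) and 157 (9 up) without homozygous replicates 1 and 2, 262 (97 up) without hemizygous replicate 1, and 109 (1 up) with only the 4 libraries compared. Without hemizygous replicate 2 it was 370 (17 up), with 136 3p arms falling and 17 rising.

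Of the groups fixed in advance, all 8 5p guides of miR-17-92 and its paralogs fell (median -4.04, camera adjusted p = 8.21e-05; adjusted p = 0.838 with an estimated correlation) and 0 of the 6 3p guides passed in limma (0 at an unadjusted p under 0.05). In the chromosome 19 cluster 22 of 28 5p arms fell (23 adjusted over the list alone; median -4.09, adjusted p = 3.22e-07; adjusted p = 0.838 with an estimated correlation) and 0 of 31 3p arms passed (limma; 2 rising and 2 falling at an unadjusted p under 0.05; camera adjusted p = 0.0852). Falls were called in 2 of 5 miR-302 5p arms (3 adjusted over the list alone), 2 of 6 arms of miR-371-373, 4 of 5 Drosha-independent miRNAs, 3 of 8 neural, 1 of 5 mesoderm and endoderm, 4 of 12 fibroblast-enriched (5 adjusted over the list alone) and 3 of 5 p53-linked miRNAs, and in 1 of 2 mirtrons. Adjusted over the list alone, the remaining counts were the same. By hairpin, 147 of 186 ratios shifted, 145 toward 3p and 2 toward 5p (median 2.87, a 7.33-fold change; fry adjusted p = 6.52e-07). let-7a moved by 6.73 ± 0.55 and miR-20a by 6.65 ± 0.38, with all 11 hairpins of miR-17-92 and its paralogs (median 5.07), 25 of 28 in the chromosome 19 cluster (median 3.24), 3 of 5 in miR-302 and 3 of 3 in miR-371-373. The exceptions were miR-203b (-2.13, lost without hemizygous replicate 1) and miR-320a (-4.37). The count stayed between 138 and 152 when any 1 library was left out.

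**Figure D4:**
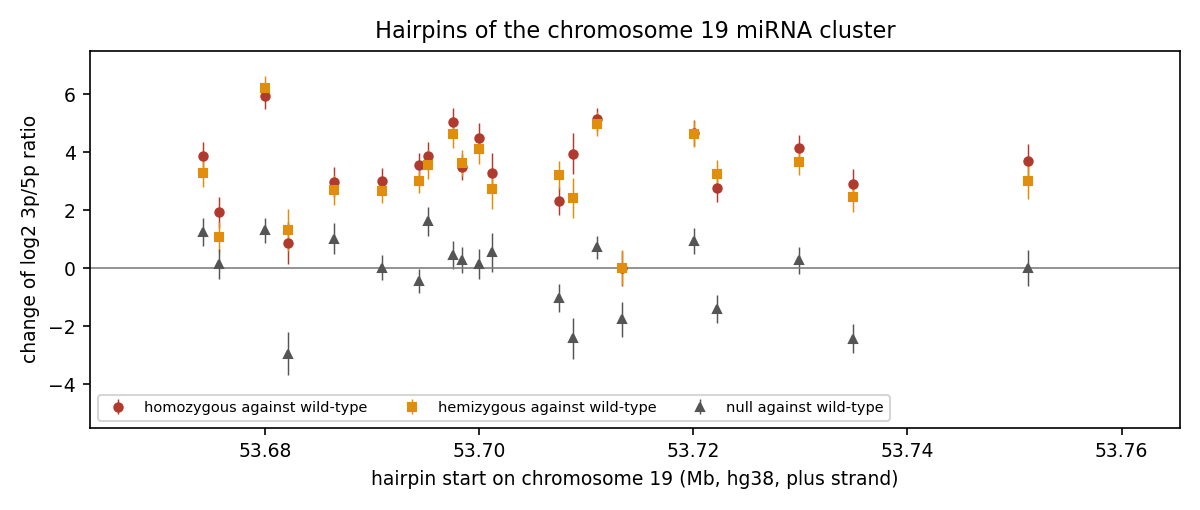
Change of the log2 3p/5p ratio against the wild type (vertical axis, log2) of 21 hairpins along the chromosome 19 miRNA cluster (horizontal axis, hg38 position), in homozygous, hemizygous and null cells. Toward 3p moved 19 hairpins in homozygous and 18 in hemizygous cells, against 2 in null cells, where 5 moved toward 5p.

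Homozygous and hemizygous cells were compared to ask whether allele dose matters. No miRNA passed: limma called 0 of 594, 7 had an unadjusted p under 0.05, and voom on recovered reads also called 0. miR-302b-3p was at -0.58, miR-302c-3p at -0.97, miR-302a-3p at -0.62, miR-367-3p at -0.86 and miR-302d-3p at -0.70 in hemizygous relative to homozygous cells, near the median of all miRNAs (-0.85). That median was 0.05 with median-ratio and with upper-quartile scaling, -0.02 with quantile normalization and -0.08 on each library's own reads, and the count of calls was 0 under each. Without hemizygous replicate 2 the count was 433, 4 up and 429 down, so this comparison rests on the library whose level stood apart. No hairpin ratio passed in limma either, with 5 at an unadjusted p under 0.05 and 3 called without hemizygous replicate 2, although over all hairpins the ratio lay slightly lower in hemizygous cells (median -0.26, fry adjusted p = 0.0242). camera placed all 3p arms (adjusted p = 2.12e-05) and the miR-371-373 cluster (adjusted p = 0.00899) below and all 5p arms (adjusted p = 0.00688) and the less abundant 5p arms (adjusted p = 0.0159) above the other miRNAs, with adjusted p = 0.944 with an estimated correlation in all of these, and fry called 0 of 18 sets (adjusted p from 0.472 to 0.509). The fold changes of the genotypes against the wild type correlated at r = 0.970 (rho 0.954) across miRNAs, which are not independent, against 0.441 to 0.560 in 100 simulated draws with no effect and the same wild-type libraries. Falls were shared by 130 miRNAs and rises by 24, with 0 opposite calls. Independent lists would share 40.4 and 2.38, which is too low a yardstick, since both lists use the same wild-type libraries. The draws took the noise of each library as independent. They therefore do not hold the structure shared by wild-type and hemizygous replicates of 1 number (r = 0.617). The 154 shared calls became 64 without wild-type replicate 1, 55 without wild-type replicate 2, 62 without homozygous replicate 1, 35 without homozygous replicate 2 and 250 without hemizygous replicate 1.

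Dicer-null cells gave the level of these miRNAs without the enzyme. On the deposited scale the pluripotency guides miR-302b-3p (-3.01), miR-302c-3p (-4.97), miR-302a-3p (-3.26), miR-367-3p (-3.56) and miR-302d-3p (-4.05) fell, but with median-ratio factors miR-302b-3p, miR-302a-3p, miR-367-3p and miR-302d-3p turned to 1.42, 1.17, 0.87 and 0.38. Median-ratio factors set the typical miRNA alike in all libraries, so they cannot show a fall shared by most miRNAs. Among the largest falls were miR-363-3p, of a miR-17-92 paralog, from 8320 ± 1633 to 49.4 ± 28.9 RPM (-7.48 ± 0.86), miR-345-5p (-7.71 ± 1.00), miR-301b-3p (-7.64), miR-1307-3p (-7.31), miR-1307-5p (-7.26) and miR-142-3p (-7.11). The falls of miR-1180-3p, miR-324-5p, miR-324-3p and miR-330-5p, also among the 10 largest, rested on 1 to 5 reads per null library. The Dicer-independent miR-451a was at -1.49 (adjusted p = 0.121), from 369 ± 125 to 128 ± 23.2 RPM, and stood at 2.92 with median-ratio factors. The rises were in miR-1248 (3.42 ± 0.93), miR-1291 (from 62.7 ± 62.7 to 536 ± 408 RPM), miR-4485-3p (3.20), miR-10395-3p (2.76), miR-10395-5p (2.55), miR-3609 (2.53), miR-12136 (2.51) and miR-4485-5p (2.25). miR-1248 (chromosome 3, 186786672 to 186786777) and miR-1291 (chromosome 12, 48654444 to 48654530) overlap the snoRNA genes SNORA81 and SNORA2C.

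In null cells limma called 526 of 594 miRNAs, 8 up and 518 down, with medians of -4.77 for 5p and -4.35 for 3p arms and -4.49 for all. The direction rested on the denominators. The other scalings set the total, the middle, the upper quartile or the whole distribution of the libraries alike. They cannot show a fall shared by most miRNAs, so a turn under them does not argue against such a fall. The median was -0.84 on each library's own miRNA reads, -0.32 with median-ratio factors, -0.33 with quantile normalization and 0.23 with upper-quartile scaling, and the calls became 80 up and 265 down, 114 and 177, 99 and 167, and 166 and 97. On the deposited scale, limma called 0 rises without wild-type replicate 2 and 0 without null replicate 2. All 28 5p and 31 3p arms of the chromosome 19 cluster, all 8 5p and 6 3p guides of miR-17-92 and its paralogs, all 6 arms of miR-371-373, 5 of 5 3p and 4 of 5 5p arms of miR-302, 12 of 12 fibroblast-enriched, 7 of 8 neural, 5 of 5 mesoderm and endoderm and 5 of 5 p53-linked miRNAs, 4 of 5 Drosha-independent miRNAs, 2 of 2 mirtrons and both let-7a arms fell, with the same counts adjusted over the list alone, but under upper-quartile scaling 31 of 54 list members or abundant miRNAs turned direction. Against other miRNAs, camera gave adjusted p = 0.336 for all 5p and 0.348 for all 3p arms, and placed the more abundant 5p arms and the more abundant 3p arms (both adjusted p = 7.72e-05) and the chromosome 19 3p arms (adjusted p = 0.01) below them (adjusted p = 0.985 with an estimated correlation for the 3 sets). The hairpin ratio changed little in the middle (median 0.27), with 81 shifts, 49 toward 3p and 32 toward 5p. Of the 115 hairpins led by 5p in the wild type 48 moved toward 3p, and of the 71 led by 3p 32 moved toward 5p. The grouping by the more abundant arm uses the wild-type values that also enter these changes. Where null values lie near the floor, an arm can fall only as far as its wild-type level allows. The low place of the more abundant arms in camera and the opposite moves of these hairpin groups can thus follow from the grouping alone. let-7a moved by 3.46 ± 0.55 and miR-17 by 0.00 ± 0.39. Without wild-type replicate 1 the count of shifts was 52. The count also rested on the 1 RPM added to each arm: it was 63 with 0.5 added, 116 with 5 added and 50 on the deposited log2 values, which add 0.5 of a read. fry called all 18 sets lower on the deposited scale (adjusted p from 0.00652 to 0.0234).

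S1344L cells were set against null cells to ask which miRNAs the mutant enzyme still makes. miR-363-3p (8.15 ± 0.86 in homozygous and 6.62 ± 0.86 in hemizygous cells relative to null) and miR-16-2-3p (7.63 and 6.35) were far above the null level on the deposited scale, whereas let-7a-5p (0.98 and 0.53), miR-34a-5p (0.18 and -0.43), miR-7-5p (0.08 and -0.70) and miR-525-5p (0.43 and -0.06) did not pass. Of the miR-302 3p arms all 5 were higher in both genotypes, with miR-302b-3p at 3.44 and 2.86, and of the chromosome 19 3p arms all 31, against 12 and 9 of its 28 5p arms (12 and 8 adjusted over the list alone). Homozygous cells differed from null cells in 465 miRNAs, 453 up and 12 down, with medians of 2.20 for 5p and 4.88 for 3p arms. Hemizygous cells differed in 385, 379 up and 6 down, with medians of 1.32 and 3.99. On this scale 121 of 227 5p arms were higher than in null cells in homozygous and 78 in hemizygous cells (limma), and 4 and 2 were lower. Of 300 3p arms 289 and 270 were higher, and 3 and 1 lower. The 5p arms named above as not passing therefore do not stand for all 5p arms. The median of all miRNAs, 3.92 and 2.89, became 0.36 and 0.15 on each library's own miRNA reads and 0.10 and 0.03 with median-ratio factors, where the calls were 194 up and 199 down, and 192 and 204; of the 5p arms 16 and 18 were then higher and 145 and 153 lower, and of the 3p arms 163 and 160 higher and 23 and 22 lower. By the 3p/5p ratio, 148 hairpins differed in homozygous cells (144 toward 3p, median 3.03, fry adjusted p = 1.34e-06) and 147 in hemizygous cells (144 toward 3p, median 2.66, fry adjusted p = 2.19e-06); on the deposited log2 values the counts were 149 and 146. Those included all 11 hairpins of miR-17-92 and its paralogs in both genotypes, and 28 and 27 of the 28 in the chromosome 19 cluster. The 5p share of RPM was -15.9 and -16.4 points from that of null cells.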

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

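Added after seeing the data were the deposited log2 values, scaling to own miRNA reads, the voom fits, and the sets with median-ratio factors and an estimated correlation or without hemizygous replicate 1; the rest was chosen before. Scaling to spike-ins was not run, since the table has 0 spike-in entries, and no filter, a log2 fold change of at least 1, and both arms past the filter removed nothing. In all, 125 alternatives of the hairpin counts stayed within 1.5 times and 4 did not; for miRNA counts it was 131 and 28, for the set tests 333 kept their side, 14 gained and 31 lost the call, and for named miRNAs 2986 kept it, 229 gained, 122 lost and 39 turned direction. The cause was not tested unless stated.

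miRNAs changed, homozygous against wild-type (191), became 338 with median-ratio, 404 with upper-quartile and 354 with quantile scaling, 372 with only the 4 libraries compared, 384 with array weights, 313 on own miRNA reads, 353 with voom weights on own reads, and 36 to 288 when 1 library was left out. miRNAs changed, hemizygous against wild-type (206), became 344, 408, 348, 109, 120, 312 and 340 in the same order, and 111 to 370. miRNAs changed, null against wild-type (526), became 291, 263 and 266 with the 3 scalings, 345 on own reads, 332 with voom weights on own reads, and 449 to 547. With 1 library left out, miRNAs changed, hemizygous against homozygous gave 0 to 433, homozygous against null 377 to 515, and hemizygous against null 285 to 518.

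Hairpins with shifted 3p/5p ratio, null against wild-type (81), became 51 at an adjusted p under 0.01, 50 on the deposited log2 values, and 52 to 97 with 1 library left out; the ranges were 140 to 157 for homozygous and 138 to 152 for hemizygous against wild-type, 0 to 3 between them, and 135 to 152 and 134 to 146 against null. The difference in the 5p share of reads, homozygous against wild-type, was -33.1 points without the 5 most abundant miRNAs and -1.22 by the share of detected miRNAs (-23.1 to -21.0 with 1 library left out), hemizygous -32.8 and -1.77 (-23.6 to -21.4), and null 3.75 and 8.55 (-7.48 to -4.76); the 5 abundant miRNAs are 3p arms. The overlap of changes in homozygous and hemizygous cells (154) lay between 35 and 250. With an estimated correlation, the set of all 5p miRNAs and the set of all 3p miRNAs were at 0.788 in homozygous and 0.838 in hemizygous cells; without hemizygous replicate 1, the set of all 5p miRNAs was at 1.47e-31, 1.51e-25 and 0.311 and the set of all 3p miRNAs at 5.26e-25, 6.40e-22 and 0.161 in homozygous, hemizygous and null cells.

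Direction turned in homozygous cells under upper-quartile scaling for miR-302a-5p (0.71), miR-92b-3p (0.89), miR-512-5p (0.79) and miR-520f-3p (0.76). In hemizygous cells it turned for miR-302b-3p with median-ratio (0.97) and upper-quartile (1.68) factors, voom weights on own reads (0.58) and without hemizygous replicate 1 (0.68; -0.97 without replicate 2), for miR-302a-3p without hemizygous replicate 2 (-0.77), for miR-367-3p with median-ratio (0.66) and upper-quartile (1.37) factors, and for miR-302d-3p with these (0.94, 1.65), quantile normalization (0.50), own reads (0.55) and voom weights on own reads (0.55). In null cells it turned with median-ratio, upper-quartile, own-read and voom own-read scaling for miR-302b-3p (1.42, 1.99, 0.90, 0.91), miR-302a-3p (1.17, 1.73, 0.65, 0.65; quantile 0.33), miR-367-3p (0.87, 1.44, 0.35, 0.34; quantile 0.14) and miR-451a (2.92, 3.48, 2.40, 2.43; quantile 3.32), with median-ratio, upper-quartile and quantile scaling for miR-302d-3p (0.38, 0.94, 0.25), and with upper-quartile scaling for miR-302c-3p (0.027). A scaling moves all miRNAs of a library together, and the medians of all miRNAs moved by the amounts given with each comparison. Scalings that set the libraries alike in level cannot show a change shared by most miRNAs. A turn under them does not argue against such a change.

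With the replicate block the counts were 206, 230, 529, 0, 474 and 392 miRNAs and 155, 154, 98, 0, 153 and 149 hairpins in the 6 comparisons, and no call on these counts or on the set of all 5p miRNAs (1.61e-30, 9.32e-26, 0.257) and the set of all 3p miRNAs (5.22e-24, 4.54e-18, 0.392) changed sides; the labels give no batch shared by libraries of 1 number. Across miRNAs, the deviations of replicate 1 from its group mean correlated at r = 0.617 between the wild-type and hemizygous groups. In the other pairs of groups r lay between -0.114 and 0.0973. Replicates of 1 number in the wild-type and hemizygous groups thus shared some structure, and its source was not tested. Depth limits the null libraries most, where 64 and 56 miRNAs had no read.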

Other observations

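In this part, the tests of small RNA fragments in hemizygous replicate 1 and of carry-over into the null libraries were chosen after the result was seen; the GC tests and the test of the denominator were planned before theirs were. In homozygous cells, where 111 5p arms fell and 56 of 300 3p arms rose, 13 3p arms fell, and all 13 also fell in hemizygous cells, where 29 did. The 13 became 3, 3, 4 and 1 without wild-type replicate 1 or 2 or homozygous replicate 1 or 2, and 26 without either hemizygous library. The 29 became 12 and 11 without wild-type replicates 1 and 2, 19 without either homozygous library and 136 without hemizygous replicate 2. Of the 13, miR-222-3p was called whichever library was left out. They include miR-222-3p (-4.24, from 10058 to 535 RPM), which represses the cell-cycle inhibitor p27, miR-1180-3p (-4.17), miR-1301-3p (-3.83), miR-324-3p (-3.31), miR-887-3p (-3.23), miR-1307-3p (-3.06) and miR-301b-3p (-2.78), named after their values were seen. Of the 13, 4 had a tested hairpin ratio, and 3 of these ratios still shifted toward 3p in homozygous cells. These were miR-1307 (1.89), miR-324 (1.54) and miR-744 (2.53), where the 5p arm thus fell further than the 3p arm. The ratio of miR-222 (-1.32) did not pass. The hairpins of the 13 had a median GC content of 56.4%, against 48.8% for all 3p arms.

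Conversely, 23 abundant 5p arms stayed within 2-fold in homozygous cells, 12 of them in hemizygous cells too, among these miR-135a-5p (0.62 in homozygous cells), miR-15b-5p (-0.15), miR-30e-5p (-0.02), miR-33a-5p (0.14) and miR-30b-5p (0.17). miR-302a-5p and miR-302c-5p were within 2-fold in homozygous cells but at -1.43 and -1.93 in hemizygous cells (adjusted p = 0.135 and 0.0529). Hemizygous against homozygous they were at -1.24 and -1.09 (both adjusted p = 0.661), beside a median of -0.85 for all miRNAs, so no difference between the genotypes is shown. These were chosen after their values were seen. Of 21 with a tested hairpin ratio 15 still shifted toward 3p, such as miR-30b (3.17) and miR-135a (3.01), and in 9 of these 15 the 3p arm itself passed as a rise. In the other 6, miR-512-3p (1.52, adjusted p = 0.161) among them, it did not pass. On other scalings the levels move with the median of all miRNAs.

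The fold changes of 3p arms declined weakly with hairpin GC content. The slope was -0.31 ± 0.09 per 10 points in homozygous cells (294 miRNAs, r = -0.209) and -0.28 ± 0.09 in hemizygous cells (r = -0.180). The miRNAs are not independent, so these errors may be too small. In 4 bins of rising GC content, 0, 1, 6 and 6 3p arms fell and 18, 14, 11 and 13 rose in homozygous cells. For 5p arms the slopes were -0.157 ± 0.125 and -0.0883 ± 0.122, within 2 standard errors of 0, and 24, 30, 27 and 30 5p arms fell over their 4 bins in homozygous cells. A GC bias of the libraries would act on both arms. The ratio between the arms of 1 hairpin had a slope of 0.108 (SE 0.168), also within 2 standard errors of 0, so neither a slope shared by the arms nor one of 3p arms alone is shown, and such a bias stays open. Slopes between replicate libraries reached -0.0538 in the wild-type and homozygous pairs, 0.257 of the slope over both arms in homozygous cells (-0.21 ± 0.10), and -0.0909 ± 0.0332 in the hemizygous pair, beside a hemizygous slope over both arms of -0.167 ± 0.0929, and 0.130 ± 0.0295 in the null pair. Replicate libraries thus differed in GC slope in some pairs, and whether library preparation varies enough stays open. A preference of the mutant enzyme for hairpins of low GC content was not tested apart from this.

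Hemizygous replicate 1 lay below replicate 2 in most miRNAs on the deposited scale. Over 224 miRNAs the SD of the log2 differences of the pair was 1.38 times that of the wild-type pair (0.679 against 0.494). Scaling shifts all miRNAs of a library alike, so this ratio was the same before and after scaling to miRNA reads, and it cannot separate the denominator from a general drop of miRNAs. The 7 miRNAs whose hairpins overlap another small RNA gene lay 3.09 higher in replicate 1 than in replicate 2 relative to the others (95% bootstrap interval 1.88 to 4.03, 10000 resamples). In the wild-type pair all 7 were also higher in replicate 1, by 1.74 (1.23 to 2.13), although its denominators differed by 1.10 times against 1.81 times in the hemizygous pair. In the homozygous pair, with denominators 1.13 times apart, 2 of the 7 were higher in replicate 1 and the median was -0.32 (-0.69 to 0.18). Of the 2 pairs with a small gap, the wild-type pair thus showed an excess in replicate 1 and the homozygous pair showed none. The null pair, with denominators of 1399490 and 751353, was not put to this test. The part of such fragments in the gap stays open. No biological explanation was tested, since the design gives the pair 1 genotype.

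Null libraries still held 165317 and 137655 miRNA reads. Fitted as a sum of the other 6 libraries, they left log2 ratios of observed to fitted reads (at least 100 fitted) with SDs of 1.41 and 1.32 over 154 and 141 miRNAs, and 1.31 and 1.17 over the 152 and 139 that were not among the 8 miRNAs that rose. The same fit of each of those 6 libraries, thinned to 137655 reads, as a sum of the other 5 left SDs of 0.154 to 0.469. The null SDs were 3.01 and 2.81 times the largest of these, which argues against carry-over from these cells or libraries as the whole source. Of the 8 that rose, 5 were matched to a hairpin gene, and 2 of these overlap another small RNA gene, in both cases a snoRNA gene. Of the 586 others 576 were matched, and 5 overlap another small RNA gene. The 8 that rose held 6.34% and 11.2% of the null reads. Fragments of other RNAs, residual processing without Dicer and carry-over as a part may each contribute and were not told apart by any value here.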
